A study of Homo sapiens with 15 samples.

How the data were processed

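RNA was measured in human primary proximal tubular epithelial cells at passage 3. Per the labels' protocols, the cells were seeded on collagen-coated plates and moved on day 1 to medium without epidermal growth factor (EGF). On day 3 they were kept in place or held for 24 h in 1% oxygen. The damaged cells then received fresh medium without EGF, either alone or with ID-8 at 1 µM, harmine at 1 µM or EGF at 10 ng/mL, and the 3 treatments lasted 48 h. The harvest time of the untreated groups was taken to be that of the treated ones and was not given in words of its own in the sources used here. Stranded libraries of polyadenylated RNA were made from 500 ng of total RNA and read from a single end over 75 bp.

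The deposited values are TPM, a transcript share corrected for length, with a single value per Ensembl gene and a separate file for each of the 15 libraries. The authors' TPM summed to 1000000 in every library, so sequencing depth is unknown and no counting interval was computed. Per the submitters' processing notes, the genome build was hg19 and the tools were Salmon, which estimates transcript abundance, and DESeq2. The versions, the role of each tool, the annotation release and the step from transcripts to genes were not given in the sources used here. Each file listed 57373 features, and 51831 of them were found by identifier in GENCODE 29, which belongs to a later genome build. That annotation was used for gene types, for the chromosome of each gene and for gene lengths, computed from the coordinates of all exons of a gene. Gene symbols came from a separate list of current names, or from GENCODE 29 where that list had none. The coordinates served no other purpose.

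Groups and replicate numbers came from the sample titles, which gave 3 replicates to each of 5 groups. The labels do not say whether the replicates came from separate donors or cultures, so the p-values measure the spread between these libraries, which may be technical. No pair of libraries held identical values. The unit of the files was left open when the design was fixed, and the branch of the design written for TPM was the one used.

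Features with at least 1 TPM in at least 3 of the 15 libraries were tested, which left 16766 features, 12529 of them protein-coding. TPM was moved to log2 after adding a pseudocount of 1. All 15 libraries entered one limma model (limma 3.58.1 in R 4.3.3) with a mean per group and no other term, and the moderated test used a mean-variance trend and robust prior estimation. The model had 10 residual and 2.16 prior degrees of freedom. The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p below 0.05 was called a change. Fold changes refer to the log2(TPM + 1) scale and understate the change of genes with low values. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, and the limma test draws on the spread of all features instead.

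Gene lists were tested with limma's camera at a preset correlation of 0.01. Of 31 lists, 27 had at least 5 tested members and were tested in each of 7 comparisons, with adjustment over the lists of a comparison. Camera with a correlation estimated from the data (statmod 1.5.0) and fry were run beside it. Counts of changed members were made with p-values adjusted over all features and adjusted over the list alone. The comparisons, lists, tests and alternatives were fixed before the data were examined, apart from those named in the closing section.

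The genes named in the text followed a rule fixed at the same time. It took 18 genes of interest in every comparison. To these it added up to 8 genes with the largest positive and up to 8 with the largest negative changes among those past the threshold, with no overlap of the 3 libraries against 3 and a mean of at least 5 TPM. It also took up to 4 members of a list with the smallest p. Where fewer than 5 features passed, the 5 with the smallest p were added as values. XIST, TSIX, Y-linked genes and features without a symbol of their own were never named.

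The overlap of calls between treatments was set against 100 simulated data sets in which unchanged groups shared the 3 hypoxia libraries, and against the overlap of independent lists. The shift of hypoxia genes was set against simulations of the same kind. The model was tested on simulated data for ID-8 against hypoxia, with 200 changed genes among 16766 features in 20 data sets. It recovered 30.7% of genes changed 1.5-fold, 65.0% of those changed 2-fold and 90.3% of those changed 4-fold, and 3.81% of its calls were false. The changed genes were drawn only from features averaging about 5 TPM or more, so recovery among lower features was not measured. Of unchanged lists of genes drawn at random, 1.4% had a camera p below 0.05. Lists of genes that vary together were not simulated, so this rate does not extend to them. For EGF against hypoxia with no simulated change, the median was 0 calls.

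The alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM, TPM rescaled by trimmed-mean factors (30% of log ratios and 5% of means trimmed), array quality weights, models of only the 6 libraries compared, the replicate number as a block, an adjusted p below 0.1, an added 2-fold threshold and each library left out in turn. A table of protein-coding features alone, rescaled to the same sum, was added after the data were seen. Apart from those gene lengths and chromosomes, no coordinates, transcripts or splice forms were analysed here. TPM shares a fixed sum, so a rise of abundant genes lowers the values of all others, and reads of near-identical genes such as the histones, HLA genes, metallothioneins and FTL pseudogenes may have been divided among them in ways that cannot be seen here. Tables were handled with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9, in Python 3.11.15.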

Results

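Human primary proximal tubular epithelial cells, which line the nephron segment that reabsorbs most of the glomerular filtrate, were profiled by RNA-seq in 5 groups of 3 libraries. An undamaged group was kept without EGF and without hypoxia. The other groups passed through 24 h at 1% oxygen and were then left untreated (the hypoxia group) or treated for 48 h with ID-8, harmine or EGF. ID-8 is described in the series title as an inhibitor of DYRK kinases and as a stimulus of tubular proliferation. Harmine is a plant β-carboline alkaloid that inhibits DYRK1A, and EGF is a mitogen of epithelial cells. Values below are mean TPM ± SD over 3 libraries (n = 3), and sequencing depth is unknown because TPM does not keep it.

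Between 21151 and 22505 features had a value above 0 in a library, and 14582 to 15025 reached 1 TPM. Protein-coding genes held 70.4% to 75.1% of the TPM. Pseudogenes of mitochondrial genes held 5.04% to 7.51%, and 0 of 8 mitochondrially encoded genes looked for were in the files. Across features, libraries of a group correlated at 0.973 to 0.981 over 15 pairs, and libraries of different groups at 0.966 to 0.980 over 90 pairs. Genes are not independent replicates in such a correlation. The leading pair of principal components held 9.83% and 9.05% of the variance. The cells expressed epithelial and tubular genes such as KRT19 at 720.2 ± 27.9 TPM and ANPEP at 393 ± 55.5 TPM in the undamaged group. LRP2, the endocytic receptor megalin, reached at most 0.018 TPM in any library, and SLC34A1, the phosphate transporter of the proximal tubule, at most 0.07 TPM, so that neither was tested.

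The comparison of hypoxia with undamaged cells asked which differences were present after oxygen deprivation and the culture that followed it. Fresh medium after day 3 is described above for the damaged cells alone, and the harvest time of the untreated groups was assumed. An effect of either could not be told apart from one of hypoxia. Genes induced by low oxygen stood higher after damage. LOX, which cross-links collagen, was at 14.8 ± 1.68 TPM against 4.69 ± 0.771 TPM (log2 change 1.47, SE 0.12, adjusted p = 3.63e-05). VEGFA, the vascular growth factor, rose 1.41-fold, and RCAN1, a feedback regulator of calcineurin, rose 1.83-fold. Complement C3 stood at 401 ± 50.5 TPM against 156 ± 11.1 TPM (adjusted p = 2.72e-05). NQO1, an antioxidant quinone reductase, fell from 226 ± 11.4 TPM to 116 ± 6.67 TPM (adjusted p = 3.63e-05). In all, 430 of 16766 features changed, 222 upward and 208 downward, and 68 of them changed at least 2-fold.

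Among 37 tested targets of hypoxia-inducible factor (HIF), 8 rose, 0 fell and 29 did not pass the test, with a median log2 change of 0.38 (camera adjusted p = 4.59e-12, and 0.0134 with an estimated correlation). Adjusted over the list alone, 19 rose. Besides LOX and VEGFA they included BNIP3, a mitophagy receptor, at 1.44-fold, HILPDA, a lipid droplet protein, at 1.62-fold and the glycolytic enzyme ALDOC at 1.83-fold. Of 35 nuclear genes of oxidative phosphorylation, 7 fell, 0 rose and 28 did not pass, and 20 fell when adjusted over the list alone. The ATP synthase subunit ATP5F1B had a log2 change of -0.38, and the cytochrome c oxidase subunits COX6A1 and COX8A fell 1.29-fold and 1.44-fold (list median -0.25, adjusted p = 3.55e-15, and 0.0283 with an estimated correlation). Of 23 genes of fatty acid oxidation, the flavoprotein subunit ETFB fell 1.49-fold and the acyl-CoA synthetase ACSL1 fell 1.63-fold, while 21 did not pass. Adjusted over the list alone, 7 of them fell (list adjusted p = 1.67e-06, and 0.00797 with an estimated correlation). Among 20 targets of NRF2, the antioxidant transcription factor, 5 fell and 15 did not pass (adjusted over the list alone, 7 fell and 1 rose), with TKT, the transketolase gene, down 1.47-fold (list adjusted p = 3.75e-07, and 0.0126 with an estimated correlation).

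Mitotic genes went the other way from the HIF targets. Of 40 tested, 5 fell, 0 rose and 35 did not pass, and 12 fell when adjusted over the list alone. BIRC5, the survivin gene, fell 2.44-fold, FOXM1, a transcription factor of mitotic genes, 1.97-fold, and PTTG1, the securin gene, 1.84-fold. With single libraries left out in turn, BIRC5 and PTTG1 kept their call in 2 of 6 fits and FOXM1 in 1. The means of the list overlapped between the libraries of the groups. The list's median was -0.40 (camera adjusted p = 3.96e-13, but adjusted p = 0.143 with an estimated correlation). CDC25B, a phosphatase that activates cyclin-dependent kinases at mitotic entry, fell from 65.7 ± 5.82 TPM to 25.8 ± 3.77 TPM. MKI67 stood at 4.94 ± 2.16 TPM against 4.79 ± 0.436 TPM and did not pass. Of 36 DNA replication genes, only MCM3, a subunit of the replicative helicase, passed, at 1.36-fold, and the list did not (adjusted p = 0.751).

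Of 29 tubular injury genes, 6 rose, 4 fell and 19 did not pass, and 8 rose and 10 fell when adjusted over the list alone. The list as a whole did not pass (adjusted p = 0.835). LCN2, which encodes the injury marker NGAL, stood at 15.6 ± 1.02 TPM against 8.62 ± 0.468 TPM (adjusted p = 0.00395). SOX9, a transcription factor of regenerating tubules, rose 1.52-fold and VIM, an intermediate filament gene, 1.17-fold, while KRT19 fell 1.34-fold. HAVCR1, which encodes the injury marker KIM-1, stood at 105 ± 9.66 TPM against 95.8 ± 4.70 TPM (adjusted p = 0.596). Among 27 inflammatory genes, 5 rose, 0 fell and 22 did not pass, with 8 up when adjusted over the list alone, and CCL2, a chemokine that draws monocytes, rose 1.35-fold (list adjusted p = 3.75e-07, but adjusted p = 0.164 with an estimated correlation). The acute-phase genes SAA1 and SAA2 rose 2.01-fold and 2.05-fold, and their near-identical sequences leave the split between them uncertain. Of 34 genes of the extracellular matrix and TGF-β response, 5 rose and 29 did not pass (adjusted over the list alone, 8 rose). The basement membrane genes COL7A1 and LAMA3 rose 2.58-fold and 1.86-fold and the collagen cross-linking enzyme LOXL2 1.41-fold (adjusted p = 0.0025, but adjusted p = 0.0832 with an estimated correlation). Of 15 YAP targets, CCN2, CCN1 and F3, the tissue factor gene, rose 1.85-fold, 1.27-fold and 1.86-fold, and the receptor tyrosine kinase AXL fell 1.54-fold, with 11 not passing and no call for the list (adjusted p = 0.0539).

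Of 24 p53 targets, 0 passed singly, 0 also when adjusted over the list alone, and 20 had positive changes, with a list median of 0.23 (camera adjusted p = 0.0025, and 0.0376 with an estimated correlation). Of 7 tested replication-dependent histone genes, H2BC12 rose 1.97-fold, 6 did not pass and all 7 had positive changes (adjusted over the list alone, 3 rose, and list adjusted p = 1.1e-04, and 0.0134 with an estimated correlation). Among the largest single changes, the metallothionein gene MT3 rose from 0.163 ± 0.283 TPM to 7.88 ± 1.90 TPM, whereas MT2A, another metallothionein gene, fell from 701 ± 171 TPM to 255 ± 57.5 TPM. The serpin SERPINB4 rose from 0.335 ± 0.0686 TPM to 5.69 ± 0.364 TPM. SPATA22 was listed at 0 in all 3 hypoxia libraries and at 5.16, 5.25 and 5.57 TPM in undamaged cells. ATF3, a stress-induced transcription factor, rose 2.40-fold, the brush-border peptidase ANPEP fell 1.88-fold, and PDZK1, a scaffold of apical transporters, fell from 132 ± 9.80 TPM to 101 ± 6.74 TPM. The remaining 18 tested lists did not pass in camera (lowest adjusted p = 0.0539). Those that fry called included YAP targets (adjusted p in fry = 6.49e-04), the interferon response (0.00854) and DYRK and CLK kinases (0.0147) as higher. The aryl hydrocarbon receptor list was called lower in fry (0.00129). Of 28 tested markers of other renal and blood cell types in 5 lists, 0 passed here in the limma test.

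Leaving out any single library lowered the count. It was 220, 245 and 323 without undamaged replicates 1, 2 and 3, and 267, 307 and 202 without hypoxia replicates 1, 2 and 3. Of the 63 changed genes that the naming rule took, 35 kept their call with any library left out, among them LOX, C3, NQO1, LCN2, RCAN1, BNIP3, HILPDA, ALDOC, CDC25B and ATP5F1B, while 28 lost it without at least 1 library. BIRC5, FOXM1, PTTG1, MCM3, SOX9, VIM, VEGFA, CCL2, COL7A1 and SPATA22 were among the latter. SPATA22 kept its call in 0 of 6 such fits and SOX9 in 1. The extracellular matrix list lost its call without hypoxia replicate 1 (adjusted p = 0.0729). After trimmed-mean rescaling, 488 features passed, 195 upward and 293 downward, so that the upward share was 40.0% against 51.6%.

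The comparison of ID-8 with untreated hypoxic cells asked what a DYRK inhibitor changed after damage. Mitotic and DNA replication genes rose as lists. TOP2A, the topoisomerase of dividing cells, rose from 7.96 ± 1.56 TPM to 28.5 ± 2.32 TPM (log2 change 1.73, SE 0.18, adjusted p = 7.24e-04), and MKI67, the proliferation marker Ki-67, from 4.94 ± 2.16 TPM to 9.47 ± 0.785 TPM (adjusted p = 0.0337). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, fell from 88.4 ± 9.22 TPM to 57.6 ± 2.79 TPM (adjusted p = 0.00359). HAVCR1 fell from 105 ± 9.66 TPM to 40.6 ± 3.52 TPM (log2 change -1.35, SE 0.10, adjusted p = 5.35e-05). In all, 385 features changed, 236 upward and 149 downward, and 79 of them at least 2-fold.

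Of 40 mitotic genes, 26 rose, 0 fell and 14 did not pass. All 40 had positive changes, and 39 rose when adjusted over the list alone (median 0.93, camera adjusted p = 1.19e-44, and 0.0186 with an estimated correlation). CENPE, a kinetochore motor, rose 3.64-fold, BIRC5 3.11-fold and TTK, a spindle checkpoint kinase, 3.06-fold. MYBL2, a transcription factor of the cell cycle, rose 2.15-fold. Of 36 DNA replication genes, 11 rose and 25 did not pass, and 27 rose when adjusted over the list alone (median 0.63, adjusted p = 9.6e-27, and 0.00507 with an estimated correlation). PCNA, the polymerase clamp, rose from 36.7 ± 2.14 TPM to 64.7 TPM (log2 change 0.80, SE 0.07), and the nucleotide synthesis genes TYMS and RRM2 rose 2.06-fold and 2.15-fold. The helicase subunit MCM4 rose 1.59-fold. MYC rose 1.49-fold, and CCND1, the cyclin D1 gene, stood at 67.7 ± 3.30 TPM against 60.7 ± 3.30 TPM (adjusted p = 0.739). Of 7 histone genes, 0 passed singly and all 7 had negative changes, with 5 down when adjusted over the list alone (median -0.74, adjusted p = 8.1e-05, and 0.0138 with an estimated correlation). The highest of these, H2BC12, stood at 19.5 ± 4.86 TPM against 28.5 ± 4.75 TPM.

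The injury genes went both ways. Of 29, 6 rose, 2 fell and 21 did not pass (adjusted over the list alone, 8 rose and 5 fell). ITGB6, an integrin subunit of injured epithelium, rose 1.77-fold, the cadherin gene CDH6 1.67-fold and the hyaluronan receptor CD44 1.27-fold, whereas HAVCR1 and LCN2 fell, with log2 changes of -1.35 and -0.58 (list adjusted p = 0.0243, but adjusted p = 0.0618 with an estimated correlation). Among 32 genes of the ERK response, 4 rose, 1 fell and 27 did not pass (adjusted over the list alone, 7 rose and 1 fell). AREG, an EGF receptor ligand, rose 1.90-fold, the ERK pathway inhibitor SPRY2 1.60-fold and the chromatin protein HMGA2 1.62-fold. EGR1, an immediate early transcription factor, fell from 15.5 ± 0.244 TPM to 6.69 ± 0.490 TPM (list adjusted p = 0.0149, but adjusted p = 0.173 with an estimated correlation). Of 13 genes of the EGF receptor family, the receptor EGFR, its relative ERBB2 and the adaptor SHC1 fell 1.27-fold, 1.35-fold and 1.31-fold and 10 did not pass, with 4 down when adjusted over the list alone (adjusted p = 0.0075, but adjusted p = 0.0767 with an estimated correlation). Of 29 genes of the ATF4 and unfolded protein response, 6 rose and 23 did not pass, with 7 up when adjusted over the list alone. ATF4 itself rose 1.28-fold and MTHFD2, an enzyme of mitochondrial folate metabolism, 1.56-fold (adjusted p = 1.41e-04, but adjusted p = 0.0586 with an estimated correlation).

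Of 20 NRF2 targets, 3 fell, 1 rose and 16 did not pass (adjusted over the list alone, 5 fell and 1 rose). FTL, the ferritin light chain, fell from 1527 ± 16.4 TPM to 827 ± 17.6 TPM (adjusted p = 2.87e-07) and NQO1 fell 1.58-fold, while AKR1C2, a ketosteroid reductase, rose 2.11-fold (list adjusted p = 0.0334, but adjusted p = 0.173 with an estimated correlation and 0.0678 after trimmed-mean rescaling). FTL has many pseudogenes, and how reads were shared among them is not known. Of 27 inflammatory genes, CCL2, C3 and NFKB1, an NF-κB subunit, fell 1.64-fold, 1.69-fold and 1.59-fold, and the neutrophil chemokine CXCL1 rose 1.53-fold. That list did not pass (adjusted p = 0.876). Among 23 proximal tubule genes, DAB2, an adaptor of endocytosis, PDZK1 and CYP27B1, which activates vitamin D, fell, with log2 changes of -0.58, -0.50 and -1.66, and 20 did not pass. Of 37 HIF targets, LOX rose 1.66-fold while BNIP3 and NDRG1 fell 1.29-fold and 1.34-fold (list adjusted p = 0.623). The DYRK and CLK kinases had 0 changed genes of 12 in the limma test, and the list did not pass in camera but was lower with ID-8 in fry (adjusted p = 0.0255). DYRK1A stood at 12.2 TPM against 16.3 TPM (log2 difference -0.41, SE 0.43) and DYRK1B at 14.4 ± 1.99 TPM against 19.1 ± 2.60 TPM. Of the 15 tested genes of interest, 9 did not pass, with adjusted p from 0.377 to 0.754. The 19 other lists did not pass in camera (lowest adjusted p = 0.145), and 0 of 28 markers of other cell types passed in the limma test. Besides the kinases, fry called the aryl hydrocarbon receptor (adjusted p = 0.00756), interferon (0.0173), YAP (0.0277) and proximal tubule (0.0471) lists lower with ID-8.

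Leaving out single libraries lowered the count to 182, 233 and 167 without ID-8 replicates 1, 2 and 3, and to 191 and 165 without hypoxia replicates 1 and 3. Of 60 changed genes that were named, 28 kept their call with any library left out, among them HAVCR1, EGR1, TOP2A, PCNA, TYMS, MYC, CDKN1A, FTL, NQO1, CCL2, C3 and ITGB6, and 32 lost it without at least 1 library. MKI67, EGFR and LCN2 were among the latter. With single libraries left out, MKI67, EGFR and CYP27B1 kept their call in 1 of 6 fits, LCN2 in 2 and NDRG1 in 0. Of the lists, NRF2 targets lost their call without hypoxia replicates 1 and 2 and ID-8 replicate 1 (adjusted p = 0.0804, 0.0544 and 0.128), the ERK response without hypoxia replicate 3 and ID-8 replicate 3 (0.119 and 0.0551) and the injury genes without ID-8 replicate 1 (0.059).

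**Figure D1:**
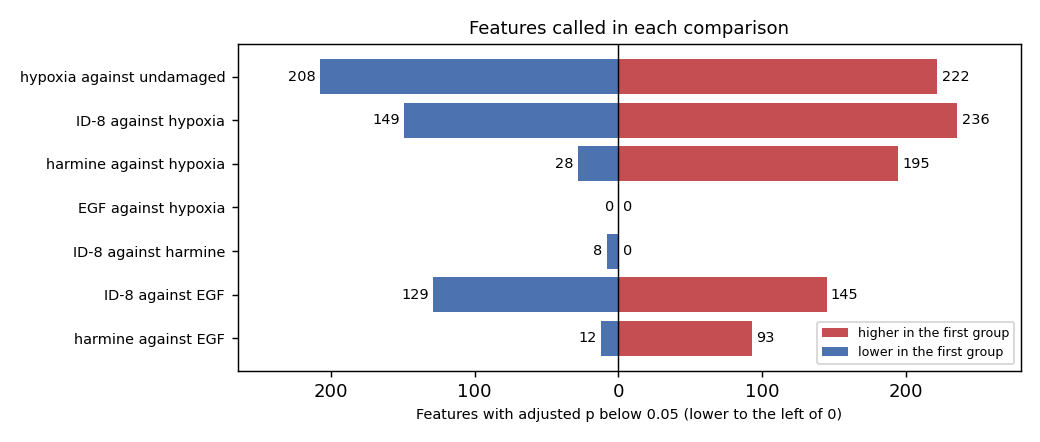
Number of features with an adjusted p below 0.05 in each of the 7 comparisons (horizontal axis, number of features), with features higher in the group named at the start of the label to the right of 0 and lower ones to the left. Hypoxia against undamaged and ID-8 against hypoxia had features in both directions (222 up and 208 down, 236 up and 149 down). Those of harmine against hypoxia were mostly upward (195 up and 28 down, or 120 up and 43 down after trimmed-mean rescaling), and EGF against hypoxia had 0.

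Harmine at the dose and time of ID-8 was compared with untreated hypoxic cells to ask whether a known DYRK1A inhibitor changed the same kinds of genes. TOP2A rose from 7.96 ± 1.56 TPM to 22.0 ± 2.14 TPM (log2 change 1.37, SE 0.18, adjusted p = 0.00474) and MKI67 from 4.94 ± 2.16 TPM to 10.0 ± 1.08 TPM (adjusted p = 0.0359). PCNA rose from 36.7 ± 2.14 TPM to 65.0 ± 2.73 TPM (adjusted p = 5.4e-04). HAVCR1 stood at 91.8 ± 7.52 TPM against 105 ± 9.66 TPM (adjusted p = 0.458). In all, 223 features changed, 195 upward and 28 downward, and 52 of them at least 2-fold. After trimmed-mean rescaling the count was 163, with 120 upward and 43 downward, and the upward share moved from 87.4% to 73.6%.

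Of 40 mitotic genes, 17 rose, 0 fell and 23 did not pass, and all 40 rose when adjusted over the list alone (median 0.94, camera adjusted p = 5.34e-36, and 0.0223 with an estimated correlation). NUSAP1, a spindle protein, rose 1.96-fold, MYBL2 2.22-fold and PRC1, which bundles the microtubules of the central spindle, 2.13-fold. Of 36 replication genes, 11 rose and 25 did not pass, with 28 up when adjusted over the list alone (median 0.71, adjusted p = 1.31e-26, and 0.00517 with an estimated correlation). TYMS rose 2.19-fold, RRM2 2.38-fold and MCM4 1.70-fold, and CDC45, a part of the replicative helicase, 2.87-fold. Further genes of the cell cycle were among the largest increases. SPC24, a kinetochore component, rose from 1.27 ± 0.142 TPM to 7.93 ± 1.27 TPM, and PCLAF, which binds PCNA, rose 2.59-fold. ASF1B, a histone chaperone, rose 2.56-fold. Of 15 G1 regulators, MYC rose 1.43-fold and 14 did not pass, with 3 up when adjusted over the list alone (adjusted p = 0.0203, but adjusted p = 0.351 with an estimated correlation). CCND1 stood at 97.4 ± 17.5 TPM against 60.7 ± 3.30 TPM (adjusted p = 0.0608), and CDKN1A at 80.7 ± 2.68 TPM against 88.4 ± 9.22 TPM (adjusted p = 0.608). The 7 histone genes all had negative changes, with 0 past the limma test singly and 0 when adjusted over the list alone (median -0.50, adjusted p = 2.08e-04, and 0.0155 with an estimated correlation).

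Of 32 ERK response genes, 8 rose, 0 fell and 24 did not pass (adjusted over the list alone, 12 rose and 1 fell). AREG rose 2.13-fold, SPRY2 1.62-fold, the early response gene IER3 1.44-fold and PHLDA1, a pleckstrin homology protein, from 24.6 ± 1.04 TPM to 37.4 ± 0.633 TPM (list adjusted p = 2.78e-08, and 0.0134 with an estimated correlation). Of 29 injury genes, CDH6, TPM1, ITGB8 and KRT19 rose 1.62-fold, 1.35-fold, 1.29-fold and 1.22-fold, and 25 did not pass (adjusted over the list alone, 12 rose and 1 fell, and list adjusted p = 0.0066, and 0.0255 with an estimated correlation). The injury list lost its call after trimmed-mean rescaling (adjusted p = 0.0613) and with protein-coding features alone (0.0508). Among 27 inflammatory genes CXCL1 rose 1.69-fold, C3 fell 1.40-fold and 25 did not pass (adjusted over the list alone, 7 rose and 1 fell, and list adjusted p = 0.0066, but adjusted p = 0.593 with an estimated correlation). Of 29 interferon response genes, 0 passed singly in the limma test, 1 fell when adjusted over the list alone and 21 had negative changes (median -0.16, adjusted p = 0.0038, and 0.0223 with an estimated correlation). Of 24 cholesterol synthesis genes, HMGCS1, which makes HMG-CoA, fell 1.34-fold and 23 did not pass, with 3 down when adjusted over the list alone (adjusted p = 1.88e-07, but adjusted p = 0.0845 with an estimated correlation). Of 29 ATF4 and unfolded protein genes, MTHFD2 rose 1.49-fold and 28 did not pass, with 2 up when adjusted over the list alone (adjusted p = 0.0137, but adjusted p = 0.187 with an estimated correlation and 0.0838 after trimmed-mean rescaling).

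FTL fell from 1527 ± 16.4 TPM to 972 ± 38.3 TPM with harmine (adjusted p = 5.26e-06). CHD3, a chromatin remodeller, fell 1.95-fold and CYP27B1 3.02-fold, and SDHA, a subunit of succinate dehydrogenase, rose 1.43-fold. SCARNA13, a small RNA of the Cajal body, was listed at 0 in all 3 harmine libraries and at 2.68 to 7.97 TPM in the hypoxia libraries. CYP1A1, the enzyme classically induced through the aryl hydrocarbon receptor, was too low to be tested. It was at 1.17, 0.351 and 0.227 TPM in the harmine libraries, at 0.08 and 0.089 TPM in 1 hypoxia and 1 undamaged library, and listed at 0 in the other 10. CYP1B1, another such enzyme, stood at 9.15 ± 0.619 TPM against 3.47 ± 1.05 TPM (adjusted p = 0.187). CLDN1, a tight junction gene placed among parietal cell markers, rose 1.44-fold, while the other 27 markers of other cell types did not pass. Pseudogenes of mitochondrial genes held 5.04% to 5.50% of the TPM in harmine libraries against 6.19% to 7.34% in hypoxia libraries. Of the 15 tested genes of interest, 13 did not pass (adjusted p from 0.0608 to 0.964), and the 17 other lists did not pass (lowest adjusted p = 0.068, for ribosomal proteins, which passed as lower after trimmed-mean rescaling at 1.49e-04).

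The count fell to 61, 68 and 70 without harmine replicates 1, 2 and 3, and to 76 and 71 without hypoxia replicates 1 and 3. Of 42 named genes that changed, 17 kept their call with any library left out. Among them were PCNA, TYMS, RRM2, MCM4, TOP2A, NUSAP1, SPC24, PCLAF, AREG, PHLDA1, MYC, CXCL1 and FTL. The other 25, MKI67 and C3 included, lost it without at least 1 library. CDC45, CHD3 and CYP27B1 kept theirs in 0 of 6 such limma fits (highest adjusted p = 0.0945, 0.129 and 0.152), and MKI67 in 1. In the list tests, leaving out hypoxia replicate 2 gave adjusted p = 0.0564 for the G1 regulators and for the ATF4 list. Leaving out hypoxia replicate 3 gave adjusted p = 0.142 for the G1 regulators and 0.283 for the inflammatory genes, and leaving out harmine replicate 3 gave 0.0649 for the latter.

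EGF against untreated hypoxic cells asked what the mitogen changed at 10 ng/mL. No gene passed: limma called 0 of 16766 features, with 1131 at an unadjusted p below 0.05 and a smallest adjusted p of 0.096. Counts were also 0 with a pseudocount of 0.1, a filter at 5 TPM, trimmed-mean rescaling or array weights, 1 with no filter and with protein-coding features alone, 12 in a model of the 6 libraries compared, 1 at an adjusted p below 0.1, and 1 without EGF replicate 2. Groups did not overlap for 1745 features, or 10.4%, where chance gives 10%. MKI67 stood at 7.60 ± 0.178 TPM with EGF against 4.94 ± 2.16 TPM, and TOP2A at 14.8 ± 3.84 TPM against 7.96 ± 1.56 TPM (log2 difference 0.80, adjusted p = 0.403).

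As a list, mitotic genes stood higher with EGF. Of 40, 39 had positive changes, 0 passed over all features and 18 passed when adjusted over the list alone (median 0.51, camera adjusted p = 1.02e-24, but adjusted p = 0.270 with an estimated correlation). TPX2, a spindle assembly factor, stood at 14.2 ± 1.01 TPM against 9.67 ± 2.15 TPM and CCNA2, the cyclin A2 gene, at 7.33 ± 1.41 TPM against 4.08 ± 1.04 TPM. Of 36 replication genes, 29 had positive changes and 0 passed, 0 also when adjusted over the list alone (median 0.19, adjusted p = 3.3e-04, but adjusted p = 0.279 with an estimated correlation). TYMS stood at 39.4 ± 6.05 TPM against 29.2 ± 2.13 TPM. The ATF4 and unfolded protein list went down (median -0.06, adjusted p = 0.0301, but adjusted p = 0.279 with an estimated correlation), with 0 members past either adjustment. Its call was lost without hypoxia replicate 1 or 3 (adjusted p = 0.0604 and 0.0765) and without EGF replicate 2 (0.163).

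Genes of the ERK response did not pass, nor did EGFR or VEGFA. DUSP6, an ERK phosphatase induced by ERK, stood at 9.60 ± 0.821 TPM against 9.52 ± 1.43 TPM, EGFR at 14.0 ± 0.377 TPM against 13.5 ± 0.478 TPM and VEGFA at 182 ± 19.3 TPM against 197 ± 15.5 TPM. The ERK response list had an adjusted p of 0.935. The features with the smallest p included TRIM6-TRIM34 (log2 difference -0.94, SE 0.12), TRIM34 (0.99, SE 0.17), ARL2 (-0.53, SE 0.10), RACGAP1 (0.84, SE 0.15) and CDC27 (0.39, SE 0.07), of which the readthrough transcript TRIM6-TRIM34 had the lowest adjusted p, 0.096. TRIM34 and the readthrough share sequence, so that their split is uncertain. The 15 tested genes of interest had adjusted p from 0.403 to 1, and the 24 other lists did not pass (lowest adjusted p = 0.0626). Some passed in camera as lower with EGF when a library was left out. These were inflammatory genes without hypoxia replicate 3 (adjusted p = 0.00105), and p53 targets and histones without hypoxia replicate 2 (0.0387 and 0.0485).

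**Figure D2:**
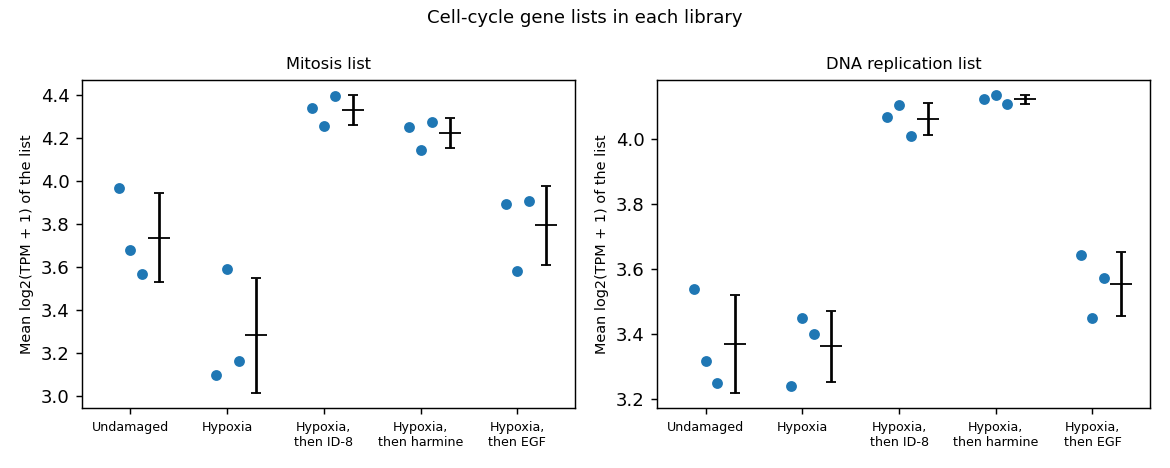
Mean log2(TPM + 1) over the 40 mitosis genes and the 36 DNA replication genes (vertical axes) in each library (dots), with the mean and SD of the 3 libraries of a group (lines and bars). The mitosis mean was 3.28 ± 0.27 in hypoxia, 3.79 ± 0.18 with EGF, 4.22 ± 0.07 with harmine and 4.33 ± 0.07 with ID-8.

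ID-8 and harmine were given at the same dose for the same time, and the direct contrast between them shares no control with another group. It called 8 features, 7 of them with a symbol of their own, and all 8 were lower with ID-8. HAVCR1 stood at 40.6 ± 3.52 TPM with ID-8 and 91.8 ± 7.52 TPM with harmine (log2 difference -1.16, SE 0.10, adjusted p = 4.7e-04). CYP27A1, a mitochondrial sterol hydroxylase, stood at 21.9 TPM against 40.6 TPM (-0.87, SE 0.09, adjusted p = 0.0018) and EGR1 at 6.69 ± 0.490 TPM against 12.3 ± 0.486 TPM (-0.79, adjusted p = 0.0128). EML1, a microtubule-associated protein gene, differed by -0.82, SLC17A1, an anion and phosphate transporter of the proximal tubule, by -0.62, CCL2 by -0.60 and CAVIN1, a coat protein of caveolae, by -0.43.

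Of 464 features called with ID-8 or harmine against hypoxia, 8 were called in the direct contrast. For 416 of them the 95% interval of the difference between the compounds lay within 1 log2 unit of 0, and for 295 within 0.58, with a median half-width of 0.26. The remaining intervals leave larger differences open. TOP2A differed by 0.36 (adjusted p = 0.536) and MKI67 by -0.07 (adjusted p = 0.939), while CDKN1A differed by -0.48 (adjusted p = 0.0683). CYP1B1 stood at 2.22 ± 0.505 TPM with ID-8 and 9.15 ± 0.619 TPM with harmine (adjusted p = 0.170). The lists of ERK response (median -0.18, adjusted p = 8.8e-04), EGF receptor family (-0.19, 0.0145), aryl hydrocarbon receptor (-0.26, 0.0145), YAP targets (-0.13, 0.0412) and inflammatory genes (-0.22, 8.8e-04) were lower with ID-8. Mitosis (0.08, 8.8e-04), cholesterol synthesis (0.09, 9.0e-04), ribosomal proteins (median 0.04) and the ATF4 list (adjusted p = 0.0486) passed as higher relative to all features, whose median difference was -0.07. With fry, which tests a list by itself, these 4 had adjusted p of 0.635, 0.277, 0.635 and 0.524, so they are not shown to be higher with ID-8. The YAP call was lost after trimmed-mean rescaling (0.142), with protein-coding features alone (0.12), and without ID-8 replicates 1, 2 and 3 (0.0615, 0.0988 and 0.0534) or harmine replicates 2 and 3 (0.0646 and 0.13). The EGF receptor family lost its call without ID-8 replicate 2 and harmine replicate 2 (0.101 and 0.0584), the inflammatory genes without ID-8 replicate 2 (0.0988) and the aryl hydrocarbon receptor list without harmine replicate 2 (0.063). None of these 9 list calls held with an estimated correlation, where the adjusted p was 0.182 for ERK, EGF receptor, aryl hydrocarbon receptor and YAP, 0.470 for inflammatory genes, 0.483 for mitosis and ribosomal proteins and 0.396 for cholesterol synthesis and ATF4. Adjusted over the list alone, 4 ERK genes, 3 of the EGF receptor family, 3 of the aryl hydrocarbon receptor, 2 YAP targets and 6 inflammatory genes were lower, and 0 genes of the other 4 lists passed in limma. The 18 remaining lists did not pass in camera (lowest adjusted p = 0.0986), although oxidative phosphorylation passed as higher with ID-8 after trimmed-mean rescaling (0.0136) and with protein-coding features alone (0.0371). Fry called 14 lists lower with ID-8 and 0 higher. Those not called in camera included tubular injury (adjusted p in fry = 0.00445), NRF2 targets (0.0211), extracellular matrix (0.0296), p53 targets (0.0314), proximal tubule and fatty acid oxidation (0.0373 for each), G1 regulators (0.0417), and DYRK and CLK kinases (0.0447). Fry does not set a list against all features, whose median difference was -0.07. In limma, 0 of 28 markers of other cell types passed.

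The direct count was 5 without ID-8 replicate 1, 3 without harmine replicate 1 and 4 without harmine replicate 3. HAVCR1 and CYP27A1 kept their calls with any library left out (highest adjusted p = 0.00537 and 0.0195), and the other 5 named genes lost theirs without at least 1. Trimmed-mean rescaling gave 10 calls, 3 of them higher with ID-8, and protein-coding features alone gave 12, with 4 higher.

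**Figure D3:**
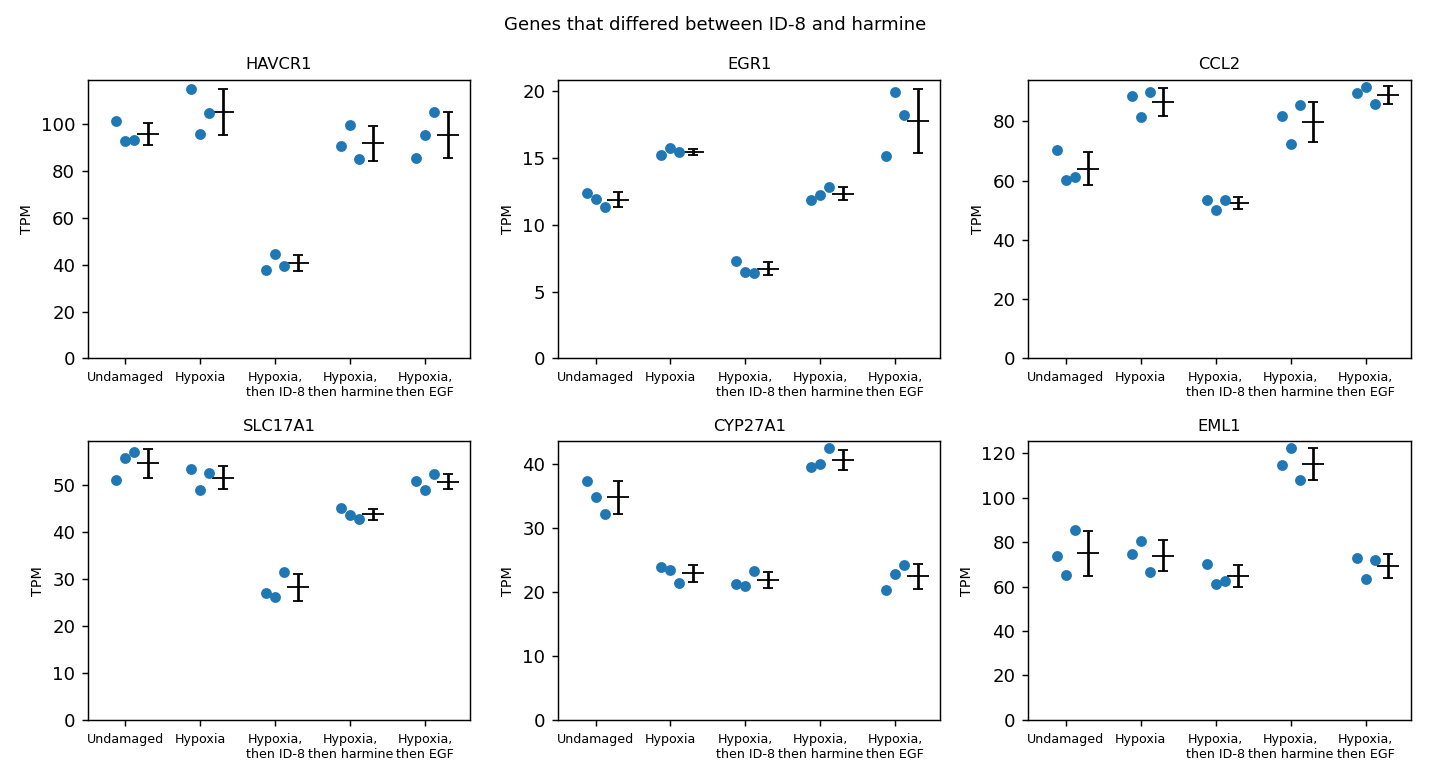
TPM of 6 genes that differed between ID-8 and harmine (vertical axes, from 0) in each library of the 5 groups (dots), with the mean and SD of 3 libraries (lines and bars). HAVCR1 lay between 37.8 and 44.6 TPM with ID-8 and between 84.9 and 115 TPM in the hypoxia, harmine and EGF groups.

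The overlap of the treatments against hypoxia was counted directly. ID-8 and harmine shared 144 called features, 129 upward, 15 downward and 0 in opposite directions. They included TOP2A, PCNA, TYMS, RRM2, MYC, AREG, CDH6, F3 and MTHFD2 among the increases and FTL, C3 and CYP27B1 among the decreases. With single libraries left out, CYP27B1 kept its call in 1 of 6 fits with ID-8 and 0 of 6 with harmine. Simulated unchanged groups that shared the 3 hypoxia libraries gave a median of 0 and at most 2 shared calls. Unchanged groups yield few calls at all, so this does not measure what shared controls add to treatments with real changes. Independent lists of these sizes would share 2.74 upward and 0.249 downward, but such lists share no controls. Part of the excess may come from the shared controls, since 3 libraries cannot be split into parts of at least 2, and the size of that part was not estimated. The covariance of the log2 changes across genes was 0.123, within the simulated range of 0.0428 to 0.146, and exceeded the simulated mean of 0.0958 by 0.0277. The covariances with EGF, 0.107 for ID-8 and 0.112 for harmine, were also within the range of theirs.

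Of the 430 features called in hypoxia against undamaged, 301 (70.0%) lay nearer to the undamaged mean with ID-8, 299 (69.5%) with harmine and 275 (64.0%) with EGF. Simulated unchanged treatments gave medians of 67.1%, 66.2% and 67.5%, because the hypoxia libraries enter both contrasts, and 32, 32 and 66 of 100 draws were as high. By this share no treatment went beyond the simulation. The median fraction of the hypoxia change undone was 0.22 with ID-8, 0.199 with harmine and 0.079 with EGF, against simulated medians of 0.09, 0.08 and 0.102 and upper ends of the central 95% of draws at 0.169, 0.204 and 0.188. On that measure ID-8 lay above the simulated range and the others did not. The simulated sets held a median of 663.5 changed features against 430, so their fractions come from unlike sets, and whether ID-8 moved these genes as a set is left open.

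The compounds were also set directly against EGF. ID-8 differed in 274 features, 145 higher and 129 lower, with 36 at least 2-fold, and harmine in 105, 93 higher and 12 lower, with 15 at least 2-fold. PCNA stood at 39.7 ± 1.46 TPM with EGF, 64.7 TPM with ID-8 (adjusted p = 8.4e-04) and 65.0 ± 2.73 TPM with harmine (adjusted p = 0.0015). MYC was higher with ID-8 and with harmine than with EGF, by log2 differences of 0.59 and 0.53. Of 36 replication genes, 4 were higher with ID-8 and 5 with harmine, or 19 and 25 when adjusted over the list alone (adjusted p = 8.0e-17 and 3.47e-17, and 0.0148 and 0.0129 with an estimated correlation). Of 40 mitotic genes 3 and 1 were higher, or 22 and 12 when adjusted over the list alone (adjusted p = 8.0e-17 and 1.06e-08, but adjusted p = 0.140 and 0.261 with an estimated correlation). TOP2A was 1.91-fold higher with ID-8 than with EGF.

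The ATF4 and unfolded protein list was higher with both compounds, with 6 of 29 genes past the test for ID-8 and 1 for harmine, or 13 and 10 adjusted over the list alone (adjusted p = 4.33e-09 and 1.15e-06, and 0.0148 and 0.0180 with an estimated correlation). HERPUD1, a gene of the unfolded protein response, and TRIB3, a pseudokinase induced by ATF4, were 1.36-fold and 1.62-fold higher with ID-8. SDF2L1, an endoplasmic reticulum protein, was 1.71-fold higher with ID-8 and 1.81-fold higher with harmine. The ERK list was higher with harmine, with AREG, IER3 and PHLDA1 past the test of 32 (adjusted over the list alone, 14 higher and 1 lower, adjusted p = 1.55e-08, and 0.0129 with an estimated correlation). With ID-8, AREG and SPRY2 were higher and EGR1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.0176, but adjusted p = 0.177 with an estimated correlation). Injury genes were 6 higher and 1 lower with ID-8, or 12 and 4 adjusted over the list alone (adjusted p = 0.0209, but adjusted p = 0.0851 with an estimated correlation), and 3 higher with harmine, or 14 and 1 (adjusted p = 0.0013, and 0.0180 with an estimated correlation).

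HAVCR1 was 2.32-fold lower with ID-8 than with EGF, EGR1 2.43-fold and CCL2 1.69-fold lower, while CLDN2, a pore-forming claudin of the proximal tubule, was 2.46-fold higher (adjusted p = 9.94e-06). FTL was lower with ID-8 (1.70-fold) and harmine (1.45-fold). SHISA2 and TNFAIP3, an inhibitor of NF-κB signalling, were 2.30-fold and 2.40-fold higher with harmine. The EGF receptor family and histone lists were lower with ID-8 (adjusted p = 0.0054 and 0.0214, but adjusted p = 0.0910 and 0.0924 with an estimated correlation), with 2 and 0 genes lower both over all features and adjusted over the list alone. With harmine, G1 regulators and inflammatory genes were higher (adjusted p = 0.0138 and 1.36e-05, but both 0.261 with an estimated correlation) and so were p53 targets (adjusted p = 0.0068, but adjusted p = 0.0721 with an estimated correlation). Cholesterol synthesis genes were lower with harmine (adjusted p = 2.67e-08, but adjusted p = 0.0747 with an estimated correlation). The interferon list was lower only relative to all features, whose median difference was 0.06, since its own median was -0.03 (adjusted p = 0.0435, but adjusted p = 0.0828 with an estimated correlation and 0.179 with fry). Adjusted over the list alone, 2 G1 regulators and 8 inflammatory genes were higher with harmine, 1 inflammatory gene and 4 cholesterol genes lower, and 0 p53 and 0 interferon genes passed in limma. The 20 remaining lists for ID-8 and 17 for harmine did not pass in camera (lowest adjusted p = 0.0801 and 0.106), although ribosomal proteins passed as lower with harmine after trimmed-mean rescaling (0.0147) and with protein-coding features alone (0.0486). Fry called the aryl hydrocarbon receptor and NRF2 lists lower with ID-8 (adjusted p = 0.00838 and 0.0139) and YAP targets higher with harmine (0.0322). Among markers of other cell types, CD68, a macrophage gene, was lower with ID-8 and CLDN1 higher with harmine.

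With single libraries left out, the count for ID-8 against EGF was 108, 116 and 87 without ID-8 replicates 1, 2 and 3 and 150, 102 and 108 without EGF replicates 1, 2 and 3. That for harmine against EGF was 22, 38 and 24 without harmine replicates 1, 2 and 3 and 65, 37 and 43 without EGF replicates 1, 2 and 3. Of 56 named genes called for ID-8 against EGF, 19 kept their call with any library left out, among them HAVCR1, EGR1, CCL2, CLDN2, PCNA, MYC, HERPUD1 and FTL, and 37, TOP2A, TRIB3 and SDF2L1 included, lost it without at least 1. Of 31 for harmine against EGF, 6 kept it, among them PCNA, MYC, FTL and SHISA2, and 25 lost it, SDF2L1 and TNFAIP3 included, the latter without any of the 6. Of the lists with ID-8, the ERK response lost its call without ID-8 replicate 3 (adjusted p = 0.069) and histones without ID-8 replicate 3 and EGF replicate 2 (0.0609 and 0.109). With harmine, p53 targets lost theirs without harmine replicate 3 (0.0717), G1 regulators without EGF replicate 3 (0.095) and the interferon list without harmine replicates 2 and 3 and EGF replicates 1 and 2 (0.0842, 0.0717, 0.137 and 0.0628). After trimmed-mean rescaling, harmine against EGF had 67 calls, 49 higher and 18 lower, an upward share of 73.1% against 88.6%.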

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

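The tests of rescaling here were chosen after the result was seen, while the tests of the pseudogene and of single libraries were written before. In the direct contrast of compounds given at the same dose, 7 named genes drew attention because ID-8 and harmine differed in them: HAVCR1 (log2 difference -1.16), CYP27A1 (-0.87), EML1 (-0.82), EGR1 (-0.79), SLC17A1 (-0.62), CCL2 (-0.60) and CAVIN1 (-0.43). Against hypoxia, HAVCR1, EGR1, SLC17A1, CCL2 and CAVIN1 fell with ID-8 (-1.35, -1.10, -0.85, -0.71 and -0.35) and did not pass with harmine. CYP27A1 and EML1 rose with harmine (0.80 and 0.63) and did not pass with ID-8.

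ID-8 lowered HAVCR1 and harmine did not pass for it, although TOP2A and PCNA rose with both. Reads moved to a pseudogene could not account for it, since the rise of the HAVCR1 pseudogene was 0.0976% of the TPM that HAVCR1 lost. No single library decided it, with a highest adjusted p of 0.00537 when any of the 6 was left out, and 92.6% of the log2 difference was left after rescaling. Over the alternatives the adjusted p for HAVCR1 ran from 3.19e-04 to 0.0283. An effect of ID-8 on injury signalling that harmine lacks at this dose is a possible explanation, and a series of doses of each compound with KIM-1 protein measured would test it. Such an effect would not cover the injury list as a whole, since more of its called genes rose than fell with ID-8 against hypoxia. Against harmine the list did not pass in camera and was lower with ID-8 in fry (adjusted p = 0.00445).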

How the results depend on the processing

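Against main counts of 430 for hypoxia against undamaged, 385 for ID-8 and 223 for harmine against hypoxia, 0 for EGF, 8 for ID-8 against harmine, 274 for ID-8 and 105 for harmine against EGF, the alternatives that moved a count by more than 1.5 times were these, and the others stayed within 1.5 times. With no filter the counts were 271, 239, 116, 1, 17, 151 and 69 in that order, where more features entered the adjustment. With only the 6 libraries compared they were 68, 38, 32, 12, 18, 15 and 17, where fewer libraries estimated the spread. Why the counts for EGF against hypoxia and ID-8 against harmine rose was not tested. The 17 for harmine against EGF were 7 higher and 10 lower, unlike the upward majority of the main fit. An adjusted p below 0.1 gave 711, 627, 436, 1, 47, 452 and 225, and an added 2-fold threshold left 68, 79, 52, 0, 2, 36 and 15, as those thresholds must. ID-8 against harmine had 20 calls with a filter at 5 TPM and 35 with array weights, harmine against EGF had 67 after trimmed-mean rescaling, and EGF against hypoxia had 1 with protein-coding features alone, and the cause was not tested. With the replicate number as a block, harmine against hypoxia had 127, ID-8 against harmine 5, ID-8 against EGF 168 and the overlap of ID-8 and harmine 93. After group means were subtracted, 30 same-numbered pairs of libraries correlated at -0.052 to 0.041, and pairs with unlike numbers at -0.061 to 0.067. The values thus showed no effect shared by a replicate number, and the labels do not say whether the numbers pair the samples. With any library left out the counts ran from 202 to 323, 165 to 300, 61 to 171, 0 to 1, 3 to 10, 87 to 150 and 22 to 65, where fewer libraries were used. Of 189 list tests, 56 passed in the main setting, 21 with an estimated correlation and 69 with fry.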

Other observations

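Genes that changed with damage and again with a compound were counted after the main results were seen. Of 70 such features with ID-8, 53 moved back, 31 of them lowered by hypoxia and raised by ID-8, and 17 moved further. BIRC5 (log2 change -1.29 with hypoxia, 1.64 with ID-8), CDC25B (-1.32, 1.01), C3 (1.35, -0.75) and LCN2 (0.79, -0.58) moved back. Without at least 1 library, BIRC5 lost both of its calls and LCN2 its call with ID-8. LOX (1.47, 0.73), F3 (0.89, 0.94) and THBS1 (0.38, 0.41) rose further, and NQO1 (-0.95, -0.66) and PDZK1 (-0.37, -0.50) fell further. Of 45 with harmine, 33 moved back and 12 moved further, F3 (0.98) and TPM1 (0.43) among the latter. The hypoxia libraries enter both contrasts with opposite sign, which by itself favours a move back.

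The tests of a single EGF library and of smaller EGF changes were chosen after the result was seen, while that of the spread was written before. EGF is a mitogen, yet 0 genes were called against hypoxia while the mitosis list passed in camera at the preset correlation (adjusted p = 0.270 with an estimated correlation and 0.0955 with fry). At most 1 gene was called with an EGF library left out. Leaving out a library also lowered the count of ID-8 against hypoxia from 385 to between 165 and 300, so this cannot exclude an unlike library. On principal component 2, EGF replicate 2 lay at 44.3, and replicates 1 and 3 at 9.66 and 7.11. The median spread of the EGF libraries was 1.08 times that of the other groups, so by that measure they were hardly more variable. Over the 385 genes that ID-8 changed, the median EGF change in the direction of ID-8 was 0.14, and 3 of 100 simulated unchanged groups were as high. A smaller response of the same genes is possible but open, and more libraries per group with a time course of EGF would test it.

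The sum over the histone clusters was chosen after the result was seen, and the tests of length and paralogs were written before. The 7 histone genes fell as a list with both compounds while DNA replication genes rose, although histone transcripts usually rise in S phase. Other genes of similar length showed -6.28% of the median histone change with ID-8 and -9.4% with harmine, and the summed TPM of the list showed 102% of it with ID-8 and 84.1% with harmine, so neither length nor reads moved between listed paralogs accounts for it. The sum over 55 cluster features was 76.8 ± 3.58 TPM in hypoxia, 51.0 ± 2.38 TPM with ID-8, 58.6 ± 8.60 TPM with harmine, 61.8 ± 11.2 TPM with EGF and 48.8 ± 6.53 TPM in undamaged cells, so a lower sum was not particular to the compounds. Most such transcripts lack a poly(A) tail, so the values may follow the polyadenylated fraction, and total RNA libraries would test it.

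The split tests were chosen after the result was seen. For each comparison the 6 libraries were divided into 3 and 3 in all 10 ways, too few for a share under 0.05. Divisions that mix the groups also put any real difference into the spread within groups, which lowers their counts. The counts of the other divisions are thus no measure of how many calls chance would give. The real division called 430 features for hypoxia against undamaged (highest other 4), 385 for ID-8 (8) and 223 for harmine (6) against hypoxia, 8 for ID-8 against harmine (3), and 274 and 105 for ID-8 and harmine against EGF (3 and 2), so that 1 of 10 divisions reached the real count in each. For EGF against hypoxia the real count was 0, the highest other 3, and 10 of 10 reached it.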
